A study of Mus musculus with 48 samples.

How the data were processed

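The 48 libraries are RNA sequencing of sorted brain microglia and of whole spinal cord from C57BL/6 wild-type male mice, with 8 libraries in each of 6 groups: young, old and old repopulated in each tissue. Per the labels' protocols, mice were perfused with buffered saline, brains were dissociated with an enzymatic kit and Cd11b and Cd45 positive cells were sorted, and cords were frozen. Per the labels' protocols, polyadenylated RNA was made into libraries with a TruSeq version that does not keep the strand. The submitters' processing notes name STAR 2.5.2b and the genome build GRCm38.p5, without saying what each was used for. The tool that counted reads per gene and its annotation release are not given in the sources used here.

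The deposited counts are whole numbers of reads per gene and were used as they stand, under the Entrez identifiers of the authors. The deposited TPM values equal counts divided by gene length and rescaled per library, as tested on the tables, and served only as an alternative. The deposited FPKM values were not used here. Genes without a symbol were kept under their identifier. Gene positions were taken from the GENCODE M21 annotation of GRCm38. Library groups and replicate numbers were taken from the labels. The labels do not say whether libraries are separate animals, nor whether both tissues came from the same mice. Pairs of libraries within a group were checked for duplicates, and all 168 pairs differed by more than sampling noise (chi-square per gene from 3.88 to 253.78).

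Counts per gene were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, with TMM scaling and filterByExpr (minimum count 10, minimum total 15), separately in each tissue over all 24 libraries of its 3 groups. This left 14382 genes in microglia and 18271 in cord. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 were called. CPM are TMM-scaled unless stated. Fold changes use the default prior count of edgeR, and log2 CPM values use a prior count of 1. Differences between tissues were interaction contrasts over all 48 libraries and 19110 genes.

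Fixed gene lists were tested with camera on limma-voom values (limma 3.58.1), with a preset correlation of 0.01 between genes, for lists of at least 4 tested members, and again with an estimated correlation. The 32 lists hold 474 entries and 463 distinct genes, of which 11 are in more than 1 list, and 4 entries (Trbc2, Igkc, Ighm, Iglc2) matched no gene. They cover microglial states, interferon, antigen presentation, cytokines, complement, lysosome, lipid, cholesterol, cell cycle and p53 genes, and markers of other myeloid, lymphoid, glial, neuronal, vascular, matrix, ependymal and red blood cells that the sort or the tissue could hold. Because the old libraries enter both the age and the repopulation comparison, the count of genes changed in opposite directions was set against 20 simulations with unchanged groups, against independent lists and against a split of the old libraries by odd and even replicate number.

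The named genes follow a rule. For old against young and repopulated against old in each tissue they are the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM and no predicted or clone name, taking first those whose groups do not overlap. For repopulated against young they are 3 and 3. A panel (Csf1r, P2ry12, Tmem119, Mki67, Apoe, Cst7, Il1b, Gfap, Mbp), up to 4 members per list with the smallest adjusted p, 5 and 5 genes changed in opposite directions, and 4 genes on each side of each interaction complete it. Some genes that the rule takes are not reported here. Groups, tests, lists, the naming rule and the first set of alternatives were fixed before the data were examined.

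Alternatives were DESeq2 1.42.0 size factors, total-count scaling, no low-count filter, a stricter filter (1 CPM in 8 libraries and a mean of 2), the DESeq2 Wald test, limma-voom with quality weights, limma on log2(TPM + 1) and log2(TPM + 0.1), the replicate number as a block, and fits with only the groups compared. Added after the data had been seen were fits without repopulated cord replicate 6, without old microglia replicates 2 and 7, with the Schwann list level as a covariate, without each library in turn, and with a smooth offset on gene length and GC content, for which 92.6% of microglia genes and 85.9% of cord genes had values. A gene that was not called and changed sign under an alternative was counted as the same. Members of each list that rose or fell were counted again under each of these settings, a choice also made after the data had been seen. Libraries were checked for outliers on totals, genes detected, ribosomal and mitochondrial shares and the named genes of the panel and of the largest changes.

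The steps were tested on simulated data with 200 changed genes per tissue. For old against young microglia (13779 genes) 44% of genes changed by a log2 of 0.5 were recovered, 70% at 1, 84% at 1.5 and 92% at 2, with 7 false among 152 calls. For old against young cord (18143 genes) the shares were 64%, 92%, 100% and 100%, with 11 false among 189 calls. An unchanged contrast gave 0 calls by edgeR in each. Depth was between 15909868 and 34496308 counts per library, and its effect on the shares recovered was not tested.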

Results

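Polyadenylated RNA was sequenced from 48 libraries of C57BL/6 wild-type male mice. Microglia, the resident macrophages of the brain, were sorted as Cd11b and Cd45 positive cells, and whole spinal cord was taken as intact tissue. Each tissue had 3 groups of 8 libraries. Young mice (3 months) and old mice (23 months) received vehicle, and the old repopulated mice (23 months) received an inhibitor of Csf1r, the receptor that microglia need to survive, for 5 days and were then left for 7 days without it. The design asks how age changes each tissue and whether microglia that grow back in an old mouse differ from those they replaced. Total counts per library ran from 28373152 to 34496308 in young, 18741936 to 27755121 in old and 23808223 to 31414974 in repopulated microglia. In cord they ran from 23756093 to 32172147 in young, 22802459 to 31075737 in old and 15909868 to 33004806 in repopulated mice. Levels are given as mean ± SD of 8 libraries in CPM, and log2 fold changes with their standard error (SE). Unless stated otherwise, CPM are counts scaled to a common total after each library's total was adjusted by its TMM factor. The labels do not say that the 8 libraries of a group came from separate animals, so p-values measure the spread between these libraries.

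In old brain microglia, transcripts known from disease-associated microglia were higher and homeostatic ones lower than in young. Spp1, which encodes the secreted protein osteopontin, rose 63.4-fold, from 5.81 ± 1.97 to 371 ± 66.3 CPM (log2 5.99, SE 0.20, adjusted p = 3.5e-20). The B cell chemokine Cxcl13 went from 0.247 ± 0.385 to 31.4 ± 9.22 CPM (log2 7.06, and 8.08 without young replicate 7) and the transmembrane glycoprotein gene Gpnmb from 0.874 ± 0.614 to 46.7 ± 12.3 CPM. Of the 22 disease-associated genes, 19 rose and none fell (1 fell on log2(TPM + 1), 20 rose when adjusted over the list alone, median log2 2.41, adjusted p = 0.00015 with an estimated correlation). All 20 homeostatic genes fell (20 adjusted over the list alone, median −0.53, adjusted p = 0.00545 with an estimated correlation), among them Csf1r, at 19900 ± 1340 CPM in young and 13800 ± 1150 CPM in old microglia.

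In all, 3128 of 14382 genes tested differed between old and young microglia, 1587 higher and 1541 lower, and 785 of the rises and 26 of the falls were at least 2-fold. The other leading rises were in the macrophage elastase Mmp12 (42.3-fold), Pianp (24.8-fold) and the cholesterol 25-hydroxylase Ch25h (23.5-fold). Among genes whose groups did not overlap, the largest falls were in Rgs7bp (5.80-fold), Gpr165 (4.56-fold), the membrane metalloproteinase Mmp15 (2.61-fold), Peg10 (2.48-fold), Myo18b (2.38-fold) and Klhdc8b (2.23-fold). For each of these 12 genes the 8 old libraries lay outside the range of the 8 young ones, which follows from the naming rule, as it takes such genes first. Within the disease-associated list, Lpl rose by log2 3.10 (SE 0.11), Clec7a by 3.12 (SE 0.11), Axl by 2.90 (SE 0.11) and Cst7 by 3.48 (SE 0.16). Apoe, the main lipid carrier made by glia, went from 1310 ± 284 to 5180 ± 1570 CPM (adjusted p = 1.9e-10). In the homeostatic list P2ry12, a purinergic receptor, was 1.58-fold lower and Tmem119 1.49-fold lower.

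Interferon and antigen presentation genes also rose with age in microglia. All 23 tested type I interferon response genes rose (23 adjusted over the list alone, median 1.66, adjusted p = 0.00883 with an estimated correlation), including Ifi204 (log2 2.07, SE 0.15) and Ifit2 (1.80, SE 0.16). Of the 12 MHC class I genes 9 rose (10 adjusted over the list alone, adjusted p = 0.0271 with an estimated correlation), such as H2-D1, from 730 ± 154 to 1890 ± 296 CPM, and the class I activator Nlrc5. Of the 8 MHC class II genes 7 rose (7 adjusted over the list alone, adjusted p = 0.0282 with an estimated correlation), with H2-Aa at 290 ± 88.9 CPM in young and 1040 ± 520 CPM in old. Reads of the class I genes H2-D1, H2-K1, H2-Q4 and H2-Q7 can be shared between close copies, so their levels are less certain. Among 21 inflammatory cytokine genes 16 rose and 1 fell (17 and 2 adjusted over the list alone, adjusted p = 0.00412 with an estimated correlation), with Il1b at 7.85 ± 0.97 and 40.8 ± 23 CPM. Complement C3 rose from 17 ± 5.97 to 186 ± 42.8 CPM, and 5 of 15 complement genes rose (6 adjusted over the list alone, adjusted p = 0.0282 with an estimated correlation).

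Cholesterol synthesis and lipid handling genes rose in part. Of 19 cholesterol synthesis genes 10 rose and none fell (11 adjusted over the list alone, median 0.44, adjusted p = 0.00182 with an estimated correlation), with the regulator Srebf2 up by log2 0.75 (SE 0.07). Lipid handling had 10 rises and 3 falls among 19 genes (11 and 3 adjusted over the list alone, adjusted p = 0.00412 with an estimated correlation), led by Lpl and Fabp5. Cell cycle genes rose in 28 of 31 cases (29 adjusted over the list alone), with Mki67 at 7.74 ± 2.5 CPM in young and 28.1 ± 12.5 CPM in old; the list had adjusted p = 0.0779 with an estimated correlation. The lysosome list had 8 rises and 4 falls among 22 genes (8 and 4 adjusted over the list alone, adjusted p = 0.494 with an estimated correlation).

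Markers of other myeloid cells that fall in the same gate rose beside these groups. Of 13 neutrophil markers 11 rose (12 adjusted over the list alone, median 2.81, adjusted p = 0.0282 with an estimated correlation), among them Ngp, from 124 ± 63.9 to 1130 ± 558 CPM. Of 14 monocyte markers 11 rose (13 adjusted over the list alone, median 1.98, adjusted p = 0.0231 with an estimated correlation), for example Chil3 and Ly6c2. Border-associated macrophage markers had 7 rises and 2 falls among 14 (10 and 2 adjusted over the list alone, 11 rises by limma-voom, adjusted p = 0.122 with an estimated correlation). The myelin gene Mbp stood at 93.1 ± 24.2 CPM in young and 232 ± 71.4 CPM in old microglia. Old replicates 2 and 7 stood apart from the other old libraries on principal components after the first; without them 3037 genes differed, 2759 of them shared with the 3128. The share of higher genes was 50.7%, 60.9% with DESeq2 size factors and 39.5% on log2(TPM + 0.1). With the length and GC offset it was 65.7%, with 1837 genes higher and 959 lower. That fit shared 2384 calls with the 3128, so the number of falls depends on the setting. Ribosomal protein genes took 2.35 ± 0.21% of the counts in young and 3.46 ± 0.74% in old microglia.

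**Figure D1:**
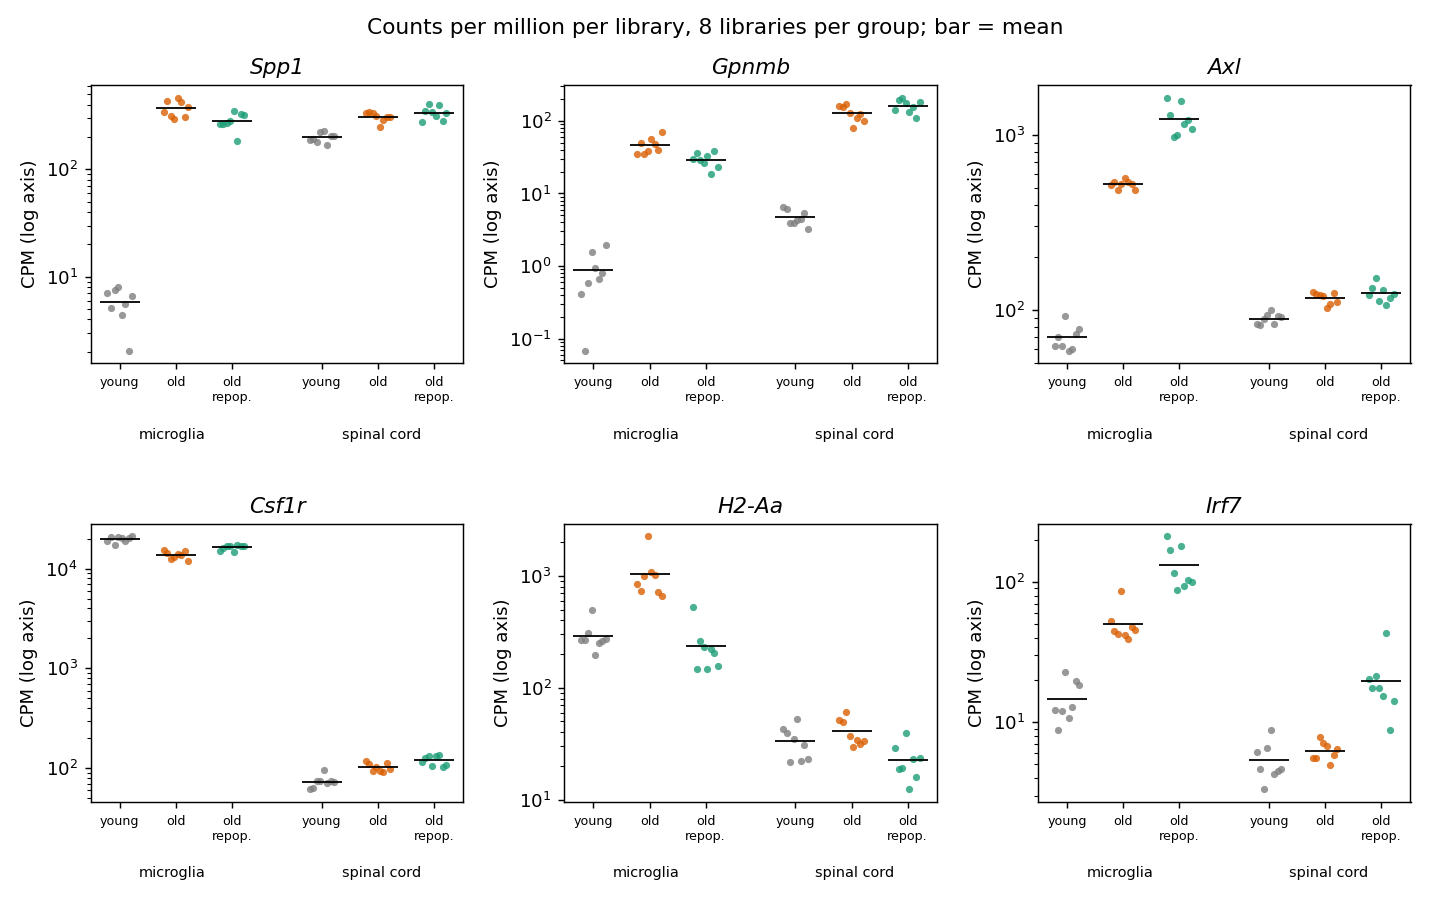
CPM after TMM scaling (log axis) of Spp1, Gpnmb, Axl, Csf1r, H2-Aa and Irf7 in each of the 48 libraries, by group, with a bar at the mean of 8. The Spp1 values of old and repopulated microglia all lie above those of young microglia, and H2-Aa is lower in repopulated than in old microglia.

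In repopulated microglia of old mice, most interferon and MHC class I genes tested were higher than in old vehicle microglia, and most MHC class II genes were lower. Of 23 interferon genes 22 rose and none fell (22 adjusted over the list alone, median 0.93, adjusted p = 0.0692 with an estimated correlation), with the short interferon-induced gene Ifi27l2a at 51.7 ± 17.5 CPM in old and 231 ± 133 CPM in repopulated microglia. Of 12 MHC class I genes 9 rose (10 adjusted over the list alone, median 0.82, adjusted p = 0.0879 with an estimated correlation); H2-D1 reached 3990 ± 599 CPM and B2m, the class I light chain, 5660 ± 754 CPM. In contrast 6 of 8 MHC class II genes fell (6 fell and 2 rose adjusted over the list alone, median −1.69, adjusted p = 0.211 with an estimated correlation), H2-Aa from 1040 ± 520 to 239 ± 125 CPM.

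Between repopulated and old microglia 2336 genes differed, 1301 higher and 1035 lower, and of those that changed at least 2-fold 98 rose and 352 fell. The largest rises were in the small nucleolar RNA host gene Zfas1 (5.64-fold, log2 2.5, SE 0.18, adjusted p = 8.5e-11), Ifi27l2a (4.47-fold), the ganglioside synthase St8sia1 (3.90-fold), the serine protease Htra3 (3.57-fold), H2-Q7 (3.13-fold) and Epb41l4aos (3.00-fold). The largest falls were in the lectin Cd209f (40.3-fold), the phospholipase Pla2g2d (19.1-fold, and 28.8-fold without repopulated replicate 5), the haemoglobin scavenger receptor Cd163 (8.41-fold), Cd209a (7.95-fold), Mgl2 (5.48-fold) and Mmp12 (5.35-fold). In each of these 12 genes the repopulated and the old libraries did not overlap. This follows from the naming rule, which takes such genes first, so larger changes with overlap may be left out. The kit does not keep the strand, so Epb41l4aos and Zfas1 cannot be told apart from overlapping transcripts of the other strand.

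Of 14 border-associated macrophage markers 11 fell and none rose (11 adjusted over the list alone, median −1.84, adjusted p = 0.103 with an estimated correlation); the mannose receptor Mrc1 stood at 218 ± 56.2 CPM in old and 44.5 ± 9.39 CPM in repopulated microglia. Neutrophil markers had 9 falls and 1 rise among 13 (9 and 1 adjusted over the list alone, adjusted p = 0.321 with an estimated correlation), and monocyte markers 6 falls and 1 rise among 14 (10 and 1 adjusted over the list alone, adjusted p = 0.326 with an estimated correlation). Of 12 endothelial markers 6 fell (10 adjusted over the list alone, adjusted p = 0.326 with an estimated correlation), among them Pecam1, from 44.3 ± 11.1 to 14.6 ± 6.23 CPM. Without old replicate 2 there were 3 endothelial falls. Monocyte and endothelial falls numbered 10 and 10 under total-count scaling, and 11 and 11 on log2(TPM + 1). Mbp fell by 1.36 on the log2 scale (SE 0.16). The falls of these markers and of the MHC class II genes were thus in the same comparison. Ribosomal protein genes took 5.62 ± 0.37% of the counts in repopulated microglia and mitochondrial transcripts 2.8 ± 0.48%, against 3.46 ± 0.74% and 2.27 ± 0.23% in old.

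The lysosome list had 12 rises and no fall among 22 genes (12 adjusted over the list alone, median 0.29, adjusted p = 0.211 with an estimated correlation), with Grn, which encodes progranulin, at 3800 ± 504 CPM in old and 6690 ± 1290 CPM in repopulated microglia. Of 14 p53 and senescence genes 4 rose (4 adjusted over the list alone, adjusted p = 0.211 with an estimated correlation), namely Ccng1, Cdkn1a, Bbc3 and Bax. The call of Bax ended under total-count scaling (log2 0.32, adjusted p = 0.089), on log2(TPM + 1) (0.19, adjusted p = 0.23), and without repopulated replicate 1 or 5 (0.38, adjusted p = 0.052 and 0.053). That of Bbc3 ended on log2(TPM + 1) (0.32, adjusted p = 0.067) and log2(TPM + 0.1) (0.34, adjusted p = 0.068). Cholesterol synthesis had 3 falls among 19 genes (4 adjusted over the list alone, adjusted p = 0.189 with an estimated correlation), with Srebf2 going from 117 ± 10.9 to 96.5 ± 5.48 CPM. The disease-associated list was not called: 4 genes rose, 4 fell and 14 did not pass (4 rose and 6 fell adjusted over the list alone, median 0.03, and −0.13 under total-count scaling), with Axl up by log2 1.24 (SE 0.10), Ccl6 down by −0.89 (SE 0.10) and Cst7 at 110 ± 27.1 and 123 ± 27 CPM. The homeostatic list was not called either, with 4 rises, 7 falls and 9 genes that did not pass (4 and 9 adjusted over the list alone). Under total-count scaling it was called lower at the preset correlation (median −0.28, adjusted p = 0.0102). The list counts of this paragraph moved with the setting. Under total-count scaling 11 lysosome genes rose and 5 fell, 10 cholesterol genes fell, 8 disease-associated genes fell, and 2 homeostatic genes rose and 13 fell. On log2(TPM + 1) 4 lysosome genes rose and 5 fell, 13 cholesterol genes fell, 2 p53 genes rose, 9 disease-associated genes fell and 2 rose, and 14 homeostatic genes fell and 2 rose. Homeostatic falls were 4 without repopulated replicate 1 or 5 or old replicate 5, 6 or 7, and cholesterol falls were 6 without repopulated replicate 4 and 5 without old replicate 1 or 5.

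Csf1r itself was 1.19-fold higher in repopulated than in old microglia (16400 ± 893 and 13800 ± 1150 CPM, log2 0.25, SE 0.06, adjusted p = 0.0019), a call that ended under total-count scaling (log2 0.08, adjusted p = 0.26) and on log2(TPM + 1), where the change was 0 (adjusted p = 0.99). The split of this comparison moved with the setting: 55.7% of the called genes were higher and 17.6% under total-count scaling, which moved the median of all genes to −0.209. It was 10.4% by limma on log2(TPM + 1), with a median of −0.212, where scaling, length and test change together.

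Against young microglia, repopulated microglia had higher disease-associated and interferon transcripts and lower homeostatic ones. Spp1 was 48.6-fold, Axl log2 4.15 (SE 0.11) and Cst7 12.5-fold above young. Of 22 disease-associated genes 20 rose (20 adjusted over the list alone, median 2.31, adjusted p = 0.00124 with an estimated correlation), and all 23 interferon genes rose (23 adjusted over the list alone, median 2.64, adjusted p = 0.0108 with an estimated correlation). Homeostatic genes fell in 17 of 20 cases (18 fell and 1 rose adjusted over the list alone, median −0.67, adjusted p = 0.0256 with an estimated correlation), with Cx3cr1, the fractalkine receptor, at 11300 ± 386 CPM in young and 6140 ± 841 CPM in repopulated microglia. MHC class I had 10 rises in 12 genes (11 adjusted over the list alone, adjusted p = 0.0256 with an estimated correlation), while in the class II list H2-DMa and H2-Oa rose and the other 6 genes did not pass (2 rose adjusted over the list alone, median −0.15). The call of H2-Oa ended on log2(TPM + 1) (log2 0.17, adjusted p = 0.28), on log2(TPM + 0.1) (0.18, adjusted p = 0.28) and with a length and GC offset (0.32, adjusted p = 0.07). On log2(TPM + 1) 1 class II gene rose and 5 fell, and without repopulated replicate 1 there were 2 falls.

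Here 4698 genes differed, 2321 higher and 2377 lower. The largest rises by the same rule were in Cxcl13 (171-fold, and 352-fold without young replicate 7), Spp1 and the acid phosphatase Acp5 (37.5-fold, at 32.6 ± 58.1 CPM, and 15.1-fold without repopulated replicate 5), and the largest falls in Cd209f (13.1-fold), Ccdc162 (12-fold, and 19.8-fold without repopulated replicate 8) and Rgs7bp (11.7-fold). Border-associated macrophage markers had 10 falls and 2 rises among 14 (10 and 2 adjusted over the list alone, adjusted p = 0.541 with an estimated correlation), and neutrophil markers 12 rises in 13 (13 adjusted over the list alone, adjusted p = 0.297 with an estimated correlation). Cell cycle genes rose in 28 of 31 cases (30 adjusted over the list alone, adjusted p = 0.144 with an estimated correlation), with Mki67 at 40.3 ± 24.2 CPM. The called genes were 49.4% higher ones, 31.8% under total-count scaling, where the median of all genes was −0.192, and 16.8% on log2(TPM + 1), where it was −0.283.

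**Figure D2:**
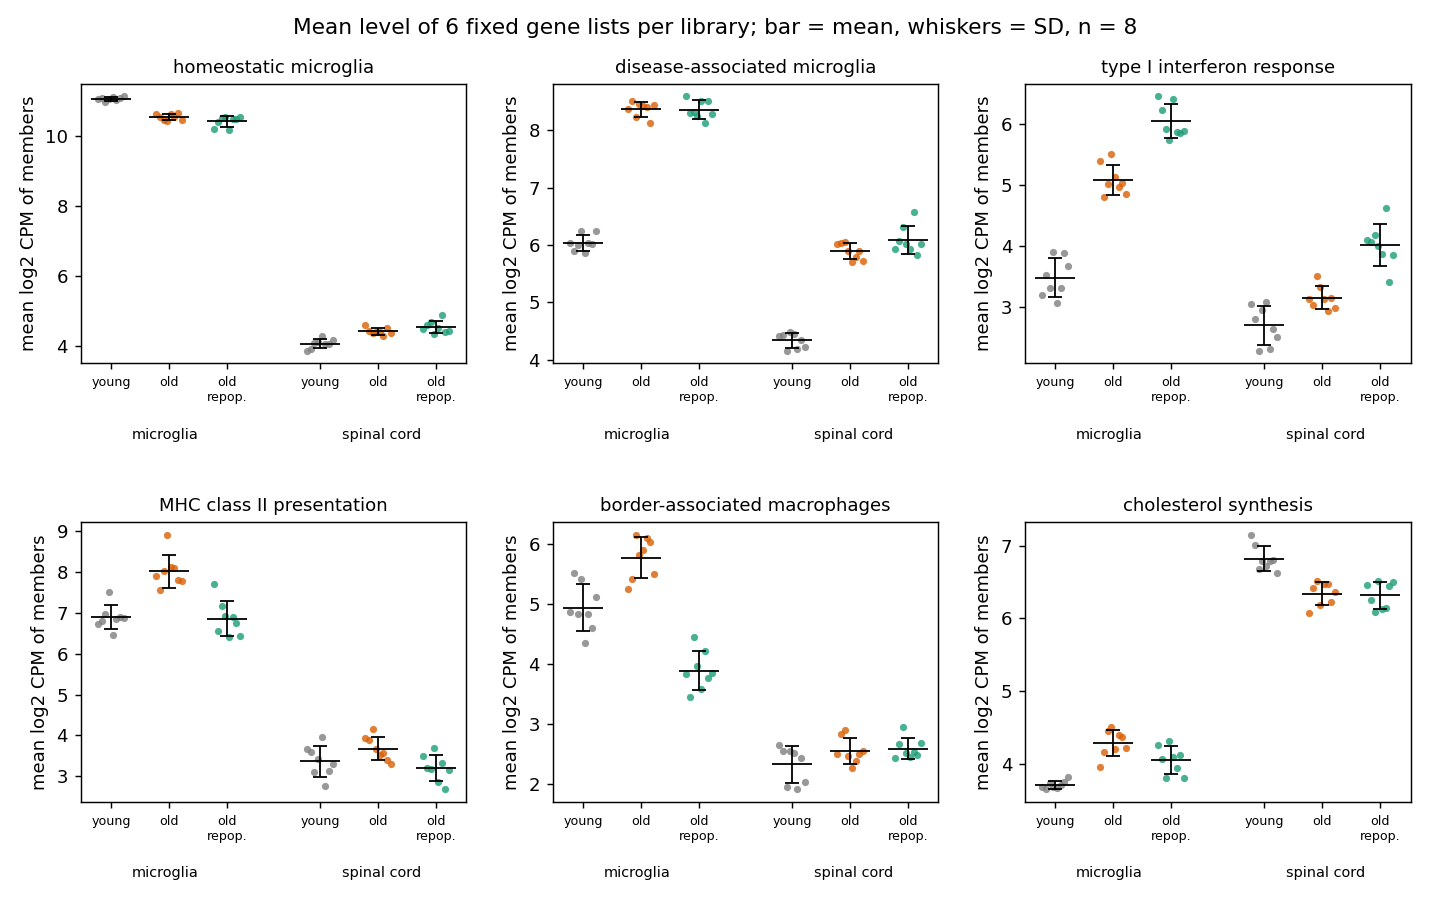
Mean log2 CPM of the tested members of 6 gene lists in each library (points), with the mean and SD of 8 libraries per group. In microglia the disease-associated and interferon lists lie higher in old and repopulated than in young libraries, and the mean of the border-associated macrophage list is lowest in the repopulated group.

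Taking the age-changed genes of microglia as a set, 474 of 3128 also changed in the opposite direction between repopulated and old libraries, and 557 moved further in the direction of age. By limma-voom the numbers were 733 opposite and 603 alike. Rises with age that then fell numbered 291 (114.2 for independent lists), falls that then rose 183 (139.4), rises that rose further 376 (143.6) and falls that fell further 181 (110.9). Mmp12 was 42.3-fold up with age and then fell by 2.42 on the log2 scale, to 7.08 ± 4.02 CPM. The interferon-induced transmembrane gene Ifitm6, the lectin Clec4d, the potassium channel Kcnj12 and Pla2g2d also rose with age and fell with repopulation. Marker lists of other myeloid cells took the same course over young, old and repopulated libraries (mean log2 CPM). Neutrophil markers stood at 4.05, 6.79 and 5.37, monocyte markers at 3.42, 5.29 and 4.4. Border-associated macrophage markers stood at 4.94, 5.77 and 3.89. How many of the 291 genes stem from such cells rather than from microglia was not tested. In the other direction Mycl, a Myc family transcription factor gene, stood at 29.4 ± 3.27 CPM in young, 15.2 ± 3.44 in old and 30.4 ± 4.09 in repopulated microglia. Smim10l2a, Tmem52, Deaf1 and Rpain also fell with age and rose with repopulation. The rise of Deaf1 lost its call by limma-voom (log2 0.55, adjusted p = 0.053), on log2(TPM + 1) (0.41, adjusted p = 0.063) and on log2(TPM + 0.1) (0.57, adjusted p = 0.072). Its fall with age lost its call with a length and GC offset (−0.48, adjusted p = 0.11) and without old replicates 2 and 7 (−0.4, adjusted p = 0.075). The rise of Rpain (log2 0.64, adjusted p = 0.029) lost its call under total-count scaling (0.47, adjusted p = 0.09), on log2(TPM + 1) (0.38), with only the groups compared in the fit (0.65) and with a length and GC offset (0.5), the adjusted p lying between 0.09 and 0.1. It also lost it without old replicate 3, 5 or 6 or repopulated replicate 5 or 7 (0.53 to 0.62, adjusted p from 0.054 to 0.084).

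The old libraries enter both comparisons, which alone gives opposite signs: 60.86% of age-changed genes had them in simulations with no repopulation effect, and 49.6% in the data. The covariance of the fold changes was −0.1509, against −0.1207 simulated. With the old libraries divided between the comparisons, 192 genes were opposite and 544 alike when even replicates served for age, and 243 and 270 when odd ones did. Rises that then fell were 129 (71.8 for independent lists) and 184 (52.8) in these divisions, and falls that then rose 63 (99.5) and 59 (50.9).

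**Figure D3:**
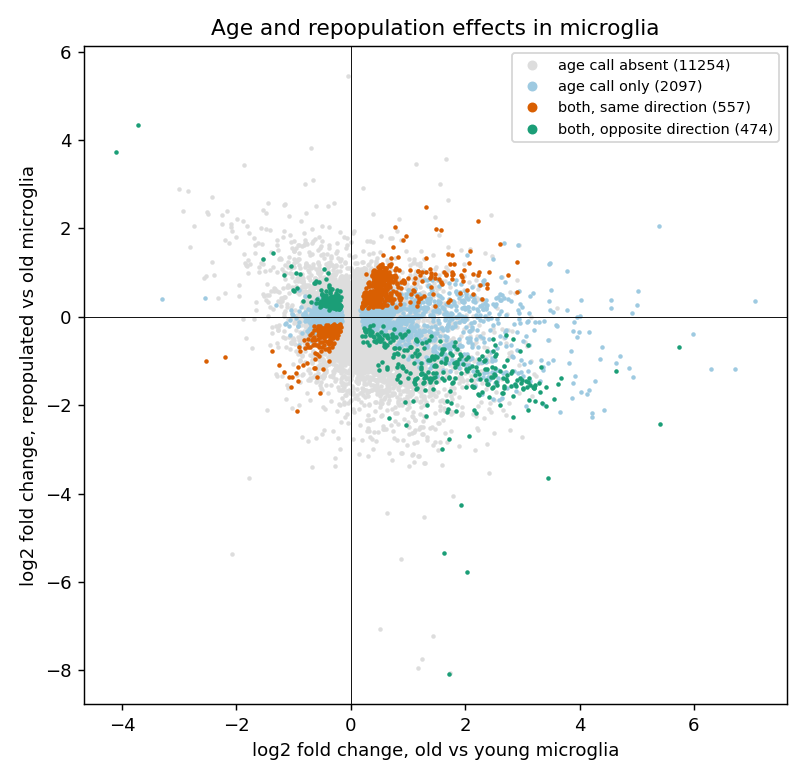
Log2 fold change between old and young microglia (x) against that between repopulated and old microglia (y) for each of 14382 genes, coloured by which comparisons called the gene. In all, 557 genes were called in both with the same sign and 474 with opposite signs (603 and 733 by limma-voom), and the old libraries are shared by both axes.

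In whole spinal cord of old mice, disease-associated microglial transcripts were higher and cholesterol synthesis transcripts lower than in young cord. Gpnmb rose 27.2-fold, from 4.73 ± 1.13 to 129 ± 32 CPM (log2 4.76, SE 0.18, adjusted p = 6.1e-15), and the integrin Itgax 19.4-fold, from 0.668 ± 0.375 to 13 ± 2.97 CPM. Of 22 disease-associated genes 16 rose and none fell (18 adjusted over the list alone, median 1.01, adjusted p = 0.00124 with an estimated correlation). All 19 cholesterol synthesis genes had negative values and 13 fell (19 adjusted over the list alone, median −0.48, adjusted p = 0.01 with an estimated correlation, 7 falls on either TPM scale); Hmgcs1, the synthase at the start of the pathway, went from 672 ± 72.6 to 402 ± 48.1 CPM.

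Of 18271 genes tested in cord 1123 differed with age, 892 higher and 231 lower (79.4% higher, and 89.6% on log2(TPM + 0.1)). Other leading rises were in the proton pump subunit Atp6v0d2 (48.5-fold), Ms4a7 (10.4-fold) and the lectin receptor Clec7a (8.36-fold). Among the largest falls were those of the lysyl oxidase Lox (2.49-fold), the oligodendrocyte precursor receptor Gpr17 (1.89-fold), Clec3b (1.87-fold), Serpind1 (1.72-fold) and Hmgcs1 (1.67-fold). For Gpnmb, Itgax and each of these genes the old and young libraries did not overlap. The naming rule takes such genes first, so larger changes with overlap may be left out. The count was 2109 without repopulated replicate 6 (all 1123 among them) and 1844 with only the 16 old and young libraries in the fit.

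In cord 11 of 15 complement genes rose (12 adjusted over the list alone, median 1.01, adjusted p = 0.00413 with an estimated correlation), C4b from 107 ± 18.2 to 279 ± 33.4 CPM. Of 19 inflammatory cytokine genes 12 rose (16 adjusted over the list alone, 4 of 7 with the stricter filter, adjusted p = 0.00124 with an estimated correlation), though several, such as Ccl3 and Ccl4, stayed near 1 CPM. Homeostatic genes rose in 10 of 20 cases (11 rose and 1 fell adjusted over the list alone, median 0.34, adjusted p = 0.0378 with an estimated correlation), with Cx3cr1 at 32.1 ± 4.41 and 60 ± 5.97 CPM and Csf1r at 73 ± 10.1 and 102 ± 10 CPM. Of 9 genes of the Csf1 receptor axis 6 rose (7 adjusted over the list alone, adjusted p = 0.00129 with an estimated correlation). The lysosome list had 9 rises in 22 (10 adjusted over the list alone, adjusted p = 0.0378 with an estimated correlation), led by Cd68. MHC class I had 10 rises in 12 (11 adjusted over the list alone, adjusted p = 0.0753 with an estimated correlation). Interferon genes rose in 6 of 23 cases (9 adjusted over the list alone, adjusted p = 0.228 with an estimated correlation), and no class II gene passed (0 adjusted over the list alone). The interferon rises were 11 without repopulated replicate 6, 12 by limma-voom, and 3 without old replicate 1, 3 or 4 or young replicate 3, 6 or 8.

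Reactive astrocyte genes had 6 rises and 1 fall among 19 (7 and 1 adjusted over the list alone, adjusted p = 0.109 with an estimated correlation), with the intermediate filament gene Gfap at 671 ± 152 and 1130 ± 142 CPM. The myelin list had 3 falls in 14, Mal, Ugt8a and Cldn11 (4 adjusted over the list alone, 7 without repopulated replicate 6, 7 by limma-voom, adjusted p = 0.405 with an estimated correlation), while Mbp stood at 9420 ± 1360 and 9250 ± 623 CPM. Markers of Schwann cells, the myelinating cells of peripheral nerve, had 3 falls in 8, among them Pmp22 and Cldn19 (3 fell and 1 rose adjusted over the list alone, adjusted p = 0.443 with an estimated correlation), in the same comparison as the cholesterol genes. The call of Cldn19 ended on both TPM scales (log2 −0.34, adjusted p = 0.12). None of 16 neuron, 8 motor neuron or 12 astrocyte markers passed by edgeR (0 adjusted over the list alone in each). Without repopulated replicate 6, 2 astrocyte markers rose and 1 fell, and 1 fell without young replicate 1 or 2 and by limma-voom.

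In the cord of repopulated old mice, interferon response transcripts were higher than in old vehicle cord. Irf7, a master regulator of interferon responses, rose 3.14-fold, from 6.26 ± 0.959 to 19.7 ± 10.1 CPM (log2 1.65, SE 0.23, adjusted p = 0.003), and Ifi27l2a 3.18-fold, from 4.24 ± 1.31 to 13.6 ± 8.12 CPM. Of 23 interferon genes 12 rose (22 adjusted over the list alone, median 0.89, adjusted p = 0.00294 with an estimated correlation). No MHC class I gene passed over all genes tested, and 12 of 12 rose adjusted over the list alone (median 0.61, adjusted p = 0.0787 with an estimated correlation). By DESeq2 and by limma-voom 5 of them rose over all genes tested, 4 without repopulated replicate 7, 2 without old replicate 3 and 1 without repopulated replicate 5 or young replicate 5.

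In all, 27 genes differed between repopulated and old cord, all higher. Of these, 9 were at least 2-fold higher. Among called genes of at least 5 CPM whose 8 and 8 libraries did not overlap, Irf7 and Ifi27l2a led. Lgals3bp (1.74-fold), Trim30a (1.65-fold), the microglial gene Fcrls (1.5-fold) and Herc6 (1.33-fold) followed. The naming rule takes genes without overlap first, so larger rises with overlap or at lower levels are not named. On log2(TPM + 1) the calls of Trim30a (log2 0.54, adjusted p = 0.26), Fcrls (0.42, adjusted p = 0.069) and Herc6 (0.25, adjusted p = 0.61) ended, as they did on log2(TPM + 0.1) (0.59, 0.43 and 0.28, adjusted p = 0.38, 0.077 and 0.6). Grn rose from 113 ± 9.92 to 171 ± 40.7 CPM. No gene fell in the edgeR test; DESeq2 called 66 genes, 61 higher and 5 lower, limma-voom 53, 52 higher and 1 lower, and 1099 genes had an unadjusted edgeR p under 0.05. MHC class II members had a median of −0.57, with none called over all genes tested (5 fell adjusted over the list alone, 2 by DESeq2, 1 by limma-voom, 2 without repopulated replicate 4, adjusted p = 0.148 with an estimated correlation). Panel genes did not pass, for example Csf1r at 102 ± 10 and 120 ± 14.2 CPM and Apoe at 2050 ± 148 and 2450 ± 1300 CPM. Repopulated replicate 6 had the highest Irf7 and Ifi27l2a; without it Irf7 changed by log2 1.39 (adjusted p = 0.00084) and Ifi27l2a by 1.35 (adjusted p = 0.017), and 31 genes were called, 26 of them among the 27. Its ribosomal protein share was 3.17%, the next highest of the group being 1.28%. The count was 57 without repopulated replicate 7, 16 without old replicate 6 and 17 without old replicate 8.

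Against young cord, repopulated cord carried both the age-linked macrophage genes and the interferon genes. Gpnmb was 34.4-fold higher, at 163 ± 33.5 CPM, Atp6v0d2 49.7-fold and Itgax 17.0-fold. Disease-associated genes rose in 19 of 22 cases (20 adjusted over the list alone, median 1.17, adjusted p = 0.00168 with an estimated correlation), interferon genes in 22 of 23 (23 adjusted over the list alone, median 1.49, adjusted p = 0.00987 with an estimated correlation) and MHC class I genes in 12 of 12 (12 adjusted over the list alone, adjusted p = 0.0191 with an estimated correlation). Cholesterol synthesis genes fell in 14 of 19 cases (19 adjusted over the list alone, median −0.48, adjusted p = 0.0191 with an estimated correlation). Gfap reached 1440 ± 381 CPM, 2.15-fold above young.

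Here 1839 genes differed, 1331 higher and 508 lower (72.4% higher, and 84.6% under total-count scaling); 1211 were called with only these groups in the fit. The largest falls by the same rule were in Lox (2.42-fold), Gpr17 (2.18-fold) and the isomerase Idi1 of cholesterol synthesis (1.79-fold). Of the 1123 age-changed cord genes 10 moved further in the direction of age with repopulation and 0 in the opposite direction by edgeR (4 by DESeq2 and 4 by limma-voom). The first number was 18 without repopulated replicate 6, 23 without repopulated replicate 7 and 6 without old replicate 4 or 8. The second was 2 without old replicate 3 or repopulated replicate 7, and 1 without young replicate 1, 2 or 3 or repopulated replicate 4 or 6. Opposite signs made up 39.4% of them, against 66.14% simulated with shared old libraries and no effect, and the covariance was 0.0056 against −0.0164.

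The response to age differed between cord and sorted microglia for many genes. Spp1 rose 63.4-fold in microglia and 1.55-fold in cord (log2 difference, cord minus microglia, −5.18, adjusted p = 2.8e-23). Young cord already held Spp1 at 199 ± 20.4 CPM (309 ± 30.5 in old), against 5.81 ± 1.97 CPM in young microglia. Its fold change in cord thus starts from a higher level. Axl rose 7.49-fold in microglia and 1.31-fold in cord. Its call in cord ended on log2(TPM + 1) (log2 0.41, adjusted p = 0.075) and log2(TPM + 0.1) (0.42, adjusted p = 0.079). Fam20c and Pianp rose 6.55-fold and 24.8-fold in microglia and did not pass in cord, where Fam20c stood at 50.8 ± 2.21 and 53 ± 1.8 CPM and Pianp at 68 ± 10.7 and 71.6 ± 6.55 CPM in young and old mice. Fcrls fell by 0.78 on the log2 scale in microglia and rose by 1.15 in cord (difference 2.09, adjusted p = 4.7e-20), and Nckap1l also fell in microglia and rose in cord; the macrophage genes Cd68 and Mpeg1 rose 5.43-fold and 4.92-fold in cord and were 1.05-fold (adjusted p = 0.56) and 1.21-fold (adjusted p = 0.0023, and 0.051 on log2(TPM + 0.1)) higher in microglia. Csf1r differed by 1.18 (adjusted p = 3e-12), falling in microglia and rising in cord. The age effect differed for 3913 of 19110 genes, 2873 of them more positive in cord; under DESeq2 size factors it was 1366 of 2696, and without repopulated cord replicate 6 it was 1719 of 3240. A level in whole cord also depends on the share of each cell type and on the level in other cells. The microglia came from brain, so region differs as well.

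The repopulation effect differed for 2107 genes, 1441 more positive in cord. Under total-count scaling it was 2819 of 3307, and without repopulated cord replicate 6 it was 1320 of 2669. With the libraries split in other ways, this test still called 21 to 1786 genes, so its adjusted p-values may be too small. Mrc1 fell by 2.29 on the log2 scale in microglia and stood at 12.1 ± 2.02 and 11.9 ± 1.41 CPM in cord (difference 2.32, adjusted p = 1.4e-08), and Sema4b, the phosphodiesterase Pde2a and Tnfaip2 also fell in microglia and did not pass in cord. The elongation factor Eef2 was 1.99-fold higher in repopulated microglia and 1.02-fold in cord (difference −0.93, adjusted p = 1.3e-10), and the arylsulfatase Arsb (2.11-fold), the syndecan Sdc3 (2.03-fold) and the poly(A)-binding protein gene Pabpc1 (1.9-fold) also rose in microglia and did not pass in cord. The rises of Irf7 (difference 0.28, adjusted p = 0.67) and Ifi27l2a (−0.45, adjusted p = 0.57) were not shown to differ between tissues.

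By the GENCODE M21 annotation of GRCm38, the genes that the account rests on most are protein coding. Spp1 (Entrez 20750) lies on chromosome 5 at 104435118 to 104441050, Axl (26362) on chromosome 7 at 25757273 to 25788705, Csf1r (12978) on chromosome 18 at 61100598 to 61132149, and Gpnmb (93695) on chromosome 6 at 49036546 to 49070929. H2-Aa (14960) lies on chromosome 17 at 34282744 to 34287823, Mrc1 (17533) on chromosome 2 at 14229392 to 14332057, Irf7 (54123) on chromosome 7 at 141262706 to 141266481 and Hmgcs1 (208715) on chromosome 13 at 119690379 to 119708260.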

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

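The B cell test was chosen after its result had been seen, and the length and GC offset and the Schwann covariate after the data had been seen. Libraries were compared within each group of 8, and 19 of 161 group and measure combinations had a library standing apart by Dixon's test, which chance gives in about 1 of 20.

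In repopulated microglia 78 of 83 ribosomal protein genes rose and none fell against old microglia (median log2 0.87), a group chosen after its values were seen, and 77 rose with age (median 0.52). With a length and GC offset the median was 0.6 (quartiles 0.48 to 0.78), and genes matched on length, GC and level had a median of 0.31 (0.15 to 0.39 over 100 draws), which argues against length and GC bias as the whole cause. Within groups the share of these genes and the total count had r = 0.02 (permutation p = 0.94, adjusted 0.94) and rho = −0.06 (p = 0.8, adjusted 0.8) over 24 libraries, and r = 0.01 without the 2 libraries farthest from the median total. This leaves library size open, since a missing correlation does not exclude it. A response to repopulation named by the design stays open, untested.

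The MHC class II list had a median of −1.69 in repopulated against old microglia and the border-associated macrophage list one of −1.84. Within groups the levels of these lists had r = 0.44 (permutation p = 0.034, adjusted 0.068) and rho = 0.56 (p = 0.0062, adjusted 0.012) over 24 libraries, and r = 0.47 without the 2 farthest, 2 relations being computed in this family, so fewer border-associated macrophages in the sort may account for part of the fall. In whole cord, old against repopulated, the class II level was 3.68 ± 0.29 and 3.2 ± 0.32 (mean log2 CPM). The macrophage level there was 2.55 ± 0.22 and 2.59 ± 0.18, so it was not lower beside the class II level. Monocyte markers also fell in the sort (median −1.03) and were not tested as a source. The B cell list had a median of −1.29 (quartiles −1.55 to −1.02), and of its 7 genes tested 0 were called by edgeR, 1 fell by DESeq2, by limma-voom, with the replicate block and without repopulated replicate 1, 2 fell under total-count scaling, on log2(TPM + 0.1), with the length and GC offset and without old replicate 1, old replicates 2 and 7 together or repopulated replicate 3, and 3 fell on log2(TPM + 1). As a list it was not called in the main fit. At the preset correlation it was called lower with the replicate block (−1.33, adjusted p = 0.00681) and without old replicates 2 and 7 (−1.52, adjusted p = 0.0317). This compared fold changes and not amounts. The B cell level was 1.85 ± 1.36 in old and 0.72 ± 0.85 in repopulated microglia (mean log2 CPM). The class II level was 8.03 ± 0.4 and 6.86 ± 0.43. With levels this far below class II, the fall of the B cell list does not show that B cells supplied the lost transcripts. Most B cells also lack Cd11b, and the sort should leave them out. A fall within microglia themselves was not tested apart from these and stays open.

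Cholesterol synthesis genes had a median of −0.48 in old against young cord, where 3 of 8 Schwann markers fell (3 fell and 1 rose adjusted over the list alone, adjusted p = 0.443 with an estimated correlation). With the Schwann list level as a covariate the median was −0.47 (adjusted p = 2.72e-20 at the preset correlation), which argues against a smaller share of Schwann cells or nerve root as the whole cause. An effect of age on the cells of the cord stays open, untested.

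Repopulated cord replicate 6 stood apart in several measures, given in CPM of library totals with the gap to the nearest library as a share of the group's range. Its ribosomal protein share was 3.17% (nearest 1.28%, gap 0.914) and its mitochondrial share 2.92% (nearest 3.78%, gap 0.551). It had Apoe at 5110 (nearest 2200, gap 0.898), Cst7 at 11.5 (nearest 6.87, gap 0.642), Ifi27l2a at 29.7 (nearest 15.1, gap 0.689) and Irf7 at 38.9 (nearest 21.8, gap 0.57). It also had the fewest genes detected of its group (22326, next 23269), without standing apart by the test. Its log2 levels relative to the cord median correlated with log2 gene length at −0.652 (next lowest of the group −0.198), a measure outside the test. In microglia, relative to the microglia median, this correlation ran from −0.12 to 0.318 in young libraries. It ran from −0.341 to 0.412 in old and from −0.381 to −0.036 in repopulated microglia. The repopulated range lay mostly below the young one, so gene length and group are not separate there. Repopulated microglia replicate 1 had Mbp at 121 (gap 0.533), H2-Q7 at 152 (gap 0.663), Cd209a at 9.2 (gap 0.558) and Mgl2 at 15.8 (gap 0.722). Replicate 2 of that group had Apoe at 7230 (gap 0.543) and replicate 5 had Htra3 at 188 (gap 0.561). Old microglia replicate 2 had the lowest total of its group, 18741936 counts (gap 0.573), and replicate 1 had Klhdc8b at 17 (gap 0.546). Young microglia replicate 7 had a ribosomal protein share of 2.79% (gap 0.537) and Cxcl13 at 1.16 (nearest 0.207, gap 0.847). Replicate 5 of that group had Ch25h at 0.409 (gap 0.652) and replicate 3 had Myo18b at 59.8 (gap 0.579). Young cord replicate 5 had Csf1r at 94.8 (gap 0.572).

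The interaction test found an age effect that differed between cord and microglia for 3913 genes and a repopulation effect that differed for 2107. For the repopulation effect, other splits of the libraries also called 21 to 1786 genes. The log2 age effect in cord minus that in microglia was 2.09 for Fcrls, 2.53 for Cd68, 2.19 for Mpeg1, 1.74 for Nckap1l, 1.18 for Csf1r, 0.93 for P2ry12, 0.93 for Tmem119 and 1.84 for Cst7. It was −5.18 for Spp1, −2.35 for Axl, −2.49 for Fam20c, −4.4 for Pianp, −1.36 for Mki67, −1.2 for Apoe, −1.26 for Il1b and −1.18 for Mbp. The repopulation effect differed by 2.05 for Sema4b, 2.32 for Mrc1, 1.87 for Pde2a, 1.44 for Tnfaip2 and 1.46 for Mbp, and by −0.93 for Eef2, −1.05 for Arsb, −0.95 for Sdc3 and −0.87 for Pabpc1.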

How the results depend on the processing

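The fits without named libraries or without each library in turn, with the Schwann covariate and with the length and GC offset were chosen after the data had been seen. Of 147 comparisons of a count with its value under another setting, 114 stayed within 1.5 times. Of 506 called gene results 505 kept their call with DESeq2 size factors, 494 with total-count scaling, 505 with the DESeq2 Wald test and 502 with limma-voom. The replicate block lost 15, 10 of them in cord, the length and GC offset 13, and no low-count filter 6. On log2(TPM + 1) 56 were lost and 3 reversed, and on log2(TPM + 0.1) 59 were lost and 3 reversed. For the counts and reversals below the cause was not tested. The 3 called results that reversed were in repopulated against old microglia, where Csf1r and Csf2rb stood at 0 and Cnp at −0.01 on each TPM scale. Cnp and Sparc, higher but not called by edgeR in repopulated against young microglia (0.15 and 0.14), were called lower on each TPM scale, at −0.18. Of simulated changes of a log2 of 0.5, 44% were recovered in microglia and 64% in cord, and depth was not varied.

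Repopulated against old microglia gave 4779 genes on log2(TPM + 1) and 4643 on log2(TPM + 0.1), and repopulated against young gave 7378 and 7478. The 474 genes that turned back in microglia were 733 by limma-voom, which turned their order against the genes that moved further (557 by edgeR, 603 by limma-voom), and 192 and 243 with the old libraries split, which leaves fewer libraries in each comparison. Old against young cord gave 2430 genes by limma-voom, 1844 with only the groups compared and 2109 without repopulated replicate 6. Repopulated against old cord gave 66 by DESeq2, 53 by limma-voom, 13 and 12 on the TPM scales and 52 with the Schwann covariate. Repopulated against young cord gave 1030 and 1003 on the TPM scales, 1211 with only the groups compared and 3110 with the Schwann covariate. Genes that turned back in cord, 0 by edgeR, were 4 by DESeq2, 4 by limma-voom, 4 with the length and GC offset, 3 with the Schwann covariate and 1 without replicate 6. Leaving out each library of a tissue in turn gave 943 to 2109 genes for old against young cord, 16 to 57 for repopulated against old cord, and 0 to 2 that turned back in cord, and moved no count by over 1.5 times in microglia. With total-count scaling the age effect differed between tissues for 2606 genes and the repopulation effect for 3307.

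With an estimated correlation the lists called were 12 of 19, 0 of 14 and 7 of 18 in microglia (old against young, repopulated against old, repopulated against young) and 8 of 19, 1 of 16 and 10 of 18 in cord. With the replicate number as a block the counts of calls were 2909, 2219 and 4610 in microglia, 953, 19 and 1408 in cord and 3832 and 2018 for the interactions and 1 gene turned back in cord. The block moved none of these counts by over 1.5 times apart from the last. Where 0 to 2 members of a list were called in one direction, that number often changed under another setting or without 1 library. Libraries with the same number did not deviate together in every pair, and at most 1 of 8 correlated best with its own number, so the numbers were not taken as pairs.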

Other observations

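The tests of overlap between tissues were chosen after the calls had been seen. Genes that rose with age in microglia and in cord overlapped: 273 of 13731 genes tested in both rose in each, where independent lists would share 81.1 (Fisher's exact p = 7.3e-83). Genes that fell in both numbered 19 (19.2 for independent lists, Fisher's exact p = 1), and 119 fell in microglia and rose in cord (82.2 for independent lists, Fisher's exact p = 2.4e-05). With repopulation 22 of the 26 genes that rose in cord also rose in microglia (2.4 for independent lists, Fisher's exact p = 2.3e-19).

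Among the other lists in microglia, immediate early and dissociation genes had 10 rises in 19 with age (6 on either TPM scale, 13 rose and 2 fell adjusted over the list alone, median 0.49, adjusted p = 0.315 with an estimated correlation). Reactive astrocyte genes had 9 rises and 1 fall in 17 (9 and 1 adjusted over the list alone, median 0.98, adjusted p = 0.0174 with an estimated correlation), endothelial markers 5 rises in 12 (7 and 1 adjusted over the list alone, adjusted p = 0.312 with an estimated correlation) and erythroid markers 3 in 5 (5 adjusted over the list alone, adjusted p = 0.513 with an estimated correlation). Endothelial rises were 9 by limma-voom and 3 without old replicate 2, 3 or 6 or young replicate 3, 5, 6, 7 or 8. Erythroid rises were 1 without old replicate 2 or 6 or young replicate 5, 6 or 7, with the replicate block, with the length and GC offset and on log2(TPM + 0.1), and 5 with only the groups compared. Mitochondrially encoded genes had 4 rises in 11 with age (4 adjusted over the list alone, adjusted p = 0.336 with an estimated correlation) and 3 with repopulation (3 adjusted over the list alone, adjusted p = 0.444 with an estimated correlation). The 4 were 1 without young replicate 2, 3 or 6 or old replicate 1 or 4, with the length and GC offset and on either TPM scale, and 2 without the low-count filter. The 3 were 1 on either TPM scale. No T and NK cell gene of 8, Schwann marker of 4 or ependymal marker of 8 was called with age by edgeR (0 adjusted over the list alone in each), and 2 T and NK cell genes were by limma-voom. Neuron, astrocyte, myelin, precursor, mural and fibroblast lists had 1, 2, 2, 2, 1 and 1 rises, the fibroblast list also had 1 fall, and the B cell list had 1 rise and 1 fall. The B cell rise, Jchain (log2 4.43), was 3.38 without old replicate 4 and 5.3 without young replicate 6, and it lost its call by limma-voom (adjusted p = 0.054). The B cell fall, Cd79b, ended with DESeq2 size factors (adjusted p = 0.052), under total-count scaling, without old replicates 2 and 7 together (0.078), and without old replicate 1, 3, 5, 7 or 8 or young replicate 4 or 6 (0.056 to 0.064).

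In cord with age, 5 of 31 cell cycle genes rose (6 adjusted over the list alone, adjusted p = 0.275 with an estimated correlation), as did 7 of 20 lipid handling genes with 1 fall (10 and 2 adjusted over the list alone, adjusted p = 0.0494 with an estimated correlation). Border-associated macrophage markers had 3 rises in 13 (4 rose and 4 fell adjusted over the list alone), monocyte markers 2 in 12 (adjusted p = 0.275 with an estimated correlation), neutrophil markers 1 in 13 (adjusted p = 0.443 with an estimated correlation), and T and NK cell genes 2 in 4 (adjusted p = 0.0551 with an estimated correlation). Cell cycle rises were 1 on either TPM scale, 8 by limma-voom, 3 with the replicate block, 2 without old replicate 1, 2 or 7 or young replicate 3, and 3 without old replicate 3 or 4 or young replicate 6 or 7. T and NK cell rises were 5 by DESeq2, 4 without repopulated replicate 6, and 1 with the replicate block and without old replicate 1, 2 or 3 or young replicate 3, 4, 6 or 7. Immediate early genes had 4 rises and 1 fall in 19 (adjusted p = 0.336 with an estimated correlation), p53 genes 2 rises in 14, precursor markers 1 rise and 1 fall, and endothelial, mural and B cell markers 1 rise each. The immediate early rises were 2 without old replicate 1, 2, 3, 4 or 6, young replicate 3, 4, 6, 7 or 8 or repopulated replicate 8. No ependymal, erythroid or mitochondrially encoded gene was called in cord with age by edgeR (0 adjusted over the list alone in each).

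Other splits of the same libraries show whether a random grouping gives as large a count. They mix libraries of both groups, which widens the spread within a split and can lower its calls. A real count above them speaks against random grouping alone. It cannot separate the condition from any other difference between the groups. For old against young microglia 1 of 100 splits, the real one, gave as many genes (3128, highest other 903), and likewise for repopulated against old (2336, 849) and repopulated against young microglia (4698, 3111). The same held in cord for old against young (1123, highest other 38), repopulated against old (27, 0) and repopulated against young (1839, 767). It also held for the interactions over 60 splits (3913, 259 and 2107, 1786). For the repopulation interaction the highest other split, 1786, came near the real 2107, so chance is not excluded there. For genes that turned back in microglia (474, highest other 94, 1 of 100 splits) the count follows the number of repopulation calls, so it does not test the turning back itself. In cord the real count was 0, which all 100 splits reach, so they decide nothing. For the number of lists called at the preset correlation chance cannot be excluded: 6, 10 and 8 of 100 splits gave as many in microglia (19, 14 and 18, highest others 21, 18 and 22), and 16, 9 and 16 in cord (19, 16 and 18, highest others 29, 24 and 25).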
